A study of Mus musculus with 22 samples.

How the data were processed

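RNA was measured in 22 ear libraries of C57BL/6 mice, WT or labelled as lacking Socs3 under keratin 5, at 2, 8 and 10 weeks of age. Per the labels' protocols, total RNA was isolated from ear specimens with TRIzol, libraries were made with the TruSeq RNA v2 kit, which does not mark strand, and single-ended reads of 50 bases were sequenced on an Illumina HiSeq instrument. The labels give the source both as keratinocytes and as ear tissue, and the protocol names whole ear specimens. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 and quantified with Cufflinks on the mouse build mm9; the version of Cufflinks, the gene annotation and any filter are not given in the sources used here. Each library was deposited as 1 FPKM value per gene symbol for 21110 genes, that is, fragments per kilobase of transcript and per mapped fragments of the library as computed by the authors. The files carry no coordinates, and the reference at hand is of another build, so only its gene names and transcript lengths were used (lengths for 14004 of the tested genes, 99%).

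FPKM values are not counts, so no count model was used. Total FPKM per library ran from 406190 to 970780, which does not measure depth. Sequencing depth in reads is unknown. Relative depth was read from the spacing of values between 0.001 and 0.05 FPKM of genes shared by libraries. The precision of single low values is not known, and an exact 0 can be a failed estimate, so genes listed at 0 are given as values per library. The sum over families of near-identical genes (keratin-associated proteins, late cornified envelope, small proline-rich, haemoglobin) may be split between copies by the authors' quantification. Small RNA genes (496 in the files, 138 tested) often lie within other genes, and without strand their reads cannot be told from those of the host. Their values are given with that limit.

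Values were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 22 libraries were tested (14139). A linear model with 6 groups of genotype and age was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, so that all groups share an estimate of the spread. Contrasts compared the labelled genotypes at each age, the ages within a genotype, and the genotype difference between ages. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Lists of marker genes of cell types and of pathways, 34 in all and each with at least 4 measured members, were tested with fry, adjusted over the lists, and with camera at a preset correlation of 0.01 and at an estimated correlation. Socs3 was also compared by an exact two-sided permutation test of mean log2(FPKM + 1). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

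Groups, tests, lists, other settings and the rule for named genes were fixed before the data were examined. The rule names Socs3, the 8 largest rises and 8 largest falls at each age among called genes whose libraries do not overlap between the groups, and from each called list the 2 called members with the largest change. For ages within a genotype and for interactions it names the 4 largest rises and falls. Unnamed gene models are passed over. Because most of the largest changes at 8 weeks were small RNA genes, a second order without them was made after the values were seen, and genes from it are said to be so where they are named. Not every gene the rule names is described, and 1 of them is not reported here.

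The other settings fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, a threshold of 1 on the absolute log2 change, a fit with only the compared groups, array quality weights, the replicate number as a block, camera in place of fry, and leaving out each library in turn. After the data were seen, 4 more were added: removal of a loess trend (span 0.5) on transcript length, leaving out the library of lowest median in every group, leaving out small RNA genes, and the Eif2s3y level as a covariate.

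Whether replicate numbers pair libraries was checked from the correlation of deviations from the group means of libraries with the same number. Only for the libraries labelled cKO at 8 and 2 weeks did every pair exceed 0.1 (r = 0.111 to 0.735). There 3 of 4 libraries correlated best with their own number, a likeness from the data and not from the labels. With the number as a block 169 genes were called there in place of 174, and the mast cell and melanocyte lists were still called by fry, though without the block neither passed with an estimated correlation (0.0876 for both). No 2 libraries held identical values, and replicates correlated at r = 0.874 to 0.977 across genes.

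The scripts were tested on simulated data with 200 of 14139 genes changed. A log2 change of 1 was recovered for 53%, 44% and 48% of genes at 2, 8 and 10 weeks. For a change of 2 it was 92%, 96% and 90%. False calls were 6, 5 and 13 (3.97%, 3.45% and 8.61% of calls). Only the shifted list was called in each. The data held 3577 to 9307 called genes per age, so these rates need not carry over.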

Results

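Gene expression was measured by RNA sequencing in ear specimens of C57BL/6 mice of 2 genotypes and 3 ages. In mice labelled cKO, Socs3, an inhibitor of cytokine signalling through JAK kinases and STAT3, was to be deleted under the control of keratin 5, a gene of basal keratinocytes. The others were wild type (WT). Specimens were taken at 2, 8 and 10 weeks after birth, with 4 libraries in each group except WT at 8 and 10 weeks, which had 3 each. The series names loss of SOCS3 from keratinocytes and chronic skin disease as its subject. The comparisons ask how the ear differed between the genotypes at each age and how that difference changed with age. Of 21110 genes in the files, 14139 reached 1 FPKM in at least 3 libraries and were tested. Levels are given as mean FPKM ± SD, with n = 4, or n = 3 for WT at 8 and 10 weeks. Changes are differences in log2(FPKM + 1) with the standard error (SE) and the Benjamini-Hochberg adjusted p of limma, and the added 1 understates the change of weakly expressed genes. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

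Gene lists fixed in advance are reported as the number of measured members that rose and fell over all genes tested, and as the number adjusted over the list alone. The adjusted p of fry asks whether the genes of a list moved, on balance, in a common direction, and does not compare them with other genes. The adjusted p with an estimated correlation comes from camera, which does compare a list with all other genes.

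The WT libraries of 8 and 10 weeks stood apart from the other 16 in their share of receptor genes above 0. Olfactory and vomeronasal receptor genes, which serve sensory neurons of the nose, were above 0 for 50.4%, 72.9% and 56.2% of 1199 genes in the WT libraries of 8 weeks and for 53.5%, 34.9% and 74.2% at 10 weeks. In the other 16 libraries the share lay between 3.25% and 7.26%. The median FPKM of tested genes was 3.16, 4.57 and 2.34 in WT at 8 weeks and 6.11, 7.10 and 5.22 at 10 weeks, against 9.18 to 9.39 in WT at 2 weeks and 5.05 to 8.99 in the libraries labelled cKO, a range that holds the WT medians of 10 weeks. Ribosomal protein genes held 28.9% to 37.7% of all FPKM in WT at 8 weeks, 19.7% to 26.1% in WT at 10 weeks, 10.5% to 10.8% in WT at 2 weeks and 14.2% to 27.3% in the libraries labelled cKO. Absolute depth is unknown because the files hold no counts. The steps between low values gave a depth relative to the shallowest library of 1.0 to 1.73. Eif2s3y, a Y-linked gene, exceeded 10 FPKM in 1 of the 4 WT libraries of 2 weeks, in 0 of the 6 WT libraries of 8 and 10 weeks, and in 2 of the 4 libraries labelled cKO at each age. The groups thus differed in their makeup of males and females.

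**Figure D1:**
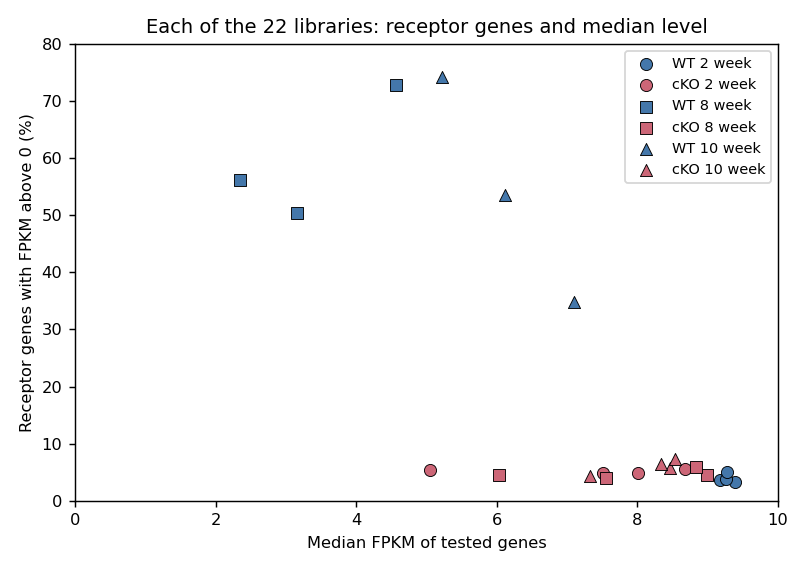
Median FPKM of the tested genes (x axis) against the percent of 1199 olfactory and vomeronasal receptor genes above 0 (y axis), with 1 point for each of the 22 libraries, by genotype label and age. The 6 WT libraries of 8 and 10 weeks lie between 34.9% and 74.2%, and all others at 7.26% or below.

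Most genes shifted together alongside these differences. The median change of all tested genes between libraries labelled cKO and WT was −0.15 at 2 weeks, 0.82 at 8 weeks and 0.24 at 10 weeks with the values as deposited. With median-of-ratios scaling, which sets the typical gene to no change, it was 0, −0.02 and −0.01. Directions are therefore given as deposited, and the scaled result stands beside each of them that it changed.

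Socs3 itself was not lower in every library labelled cKO. At 2 weeks it was 10.2, 10.3, 10.3 and 9.71 FPKM in WT and 1.25, 9.32, 12.6 and 3.51 FPKM in the libraries labelled cKO. At 8 weeks it was 0.604, 1.36 and 0.93 FPKM in WT against 1.6, 5.3, 8.47 and 6.84 FPKM. At 10 weeks it was 2.76, 4.81 and 2.02 FPKM in WT against 36.5, 29.8, 47.7 and 32.4 FPKM. The change at 2 weeks was −0.86 (SE 0.43, limma adjusted p = 0.107; exact two-sided permutation p = 0.314) and did not pass the test. It passed without the library labelled cKO replicate 2 (−1.11, adjusted p = 0.0467) or replicate 3 (−1.24, adjusted p = 0.0264). At 8 weeks Socs3 was higher in the libraries labelled cKO (1.61, SE 0.46, limma adjusted p = 0.00563; exact permutation p = 0.0571), and median-of-ratios scaling ended that call (0.91, adjusted p = 0.0972). At 10 weeks it was higher under both scalings (3.2, SE 0.46, limma adjusted p = 4.39e-05; exact permutation p = 0.0286, the smallest that 3 against 4 libraries allow). Socs3 thus went against the genotype label at 8 and 10 weeks, and every direction below is between libraries by their label. The value covers the whole gene in whole ear, where cells that do not express keratin 5 keep Socs3.

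**Figure D2:**
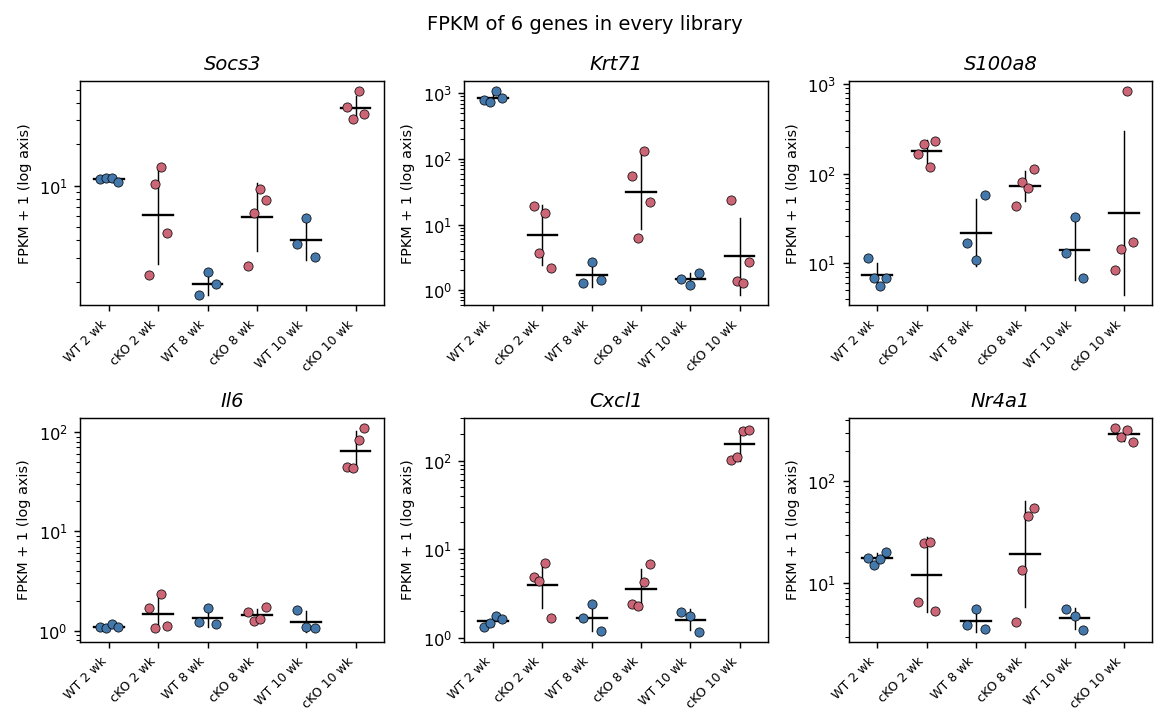
FPKM + 1 on a log axis of Socs3, Krt71, S100a8, Il6, Cxcl1 and Nr4a1 in the 22 libraries, by genotype label and age, with 1 point for each library, a bar for the group mean and a line for the SD. Socs3 is at 29.8 to 47.7 FPKM in the libraries labelled cKO at 10 weeks, the age at which Il6, Cxcl1 and Nr4a1 are also at their highest group means.

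At 2 weeks, transcripts of the hair shaft and its sheath were far lower in the libraries labelled cKO. All 26 measured genes of the hair shaft and follicle list fell (26 adjusted over the list alone), with a median change of −5.63 (fry adjusted p = 5.7e-09, adjusted p = 0.136 with an estimated correlation). Krt71, a keratin of the inner root sheath, was 859 ± 156 in WT and 8.97 ± 8.34 in cKO (−6.95, SE 0.86, limma adjusted p = 4.56e-06). Krt27, another inner root sheath keratin, went from 535 ± 93.3 to 6.51 ± 6.32 (−6.63, SE 0.75, adjusted p = 1.32e-06). Trichohyalin (Tchh), which cross-links keratin in the root sheath, went from 358 ± 73.9 to 3.65 ± 2.27 (−6.39, SE 0.57, adjusted p = 3.89e-08), and the hair keratin Krt83 from 110 ± 26.6 to 0.519 ± 0.49 (−6.23, SE 0.52, adjusted p = 1.72e-08). The other 4 of the 8 largest falls were keratin-associated proteins of the hair shaft, Krtap15 (−6.6), Krtap8-1 (−6.57), Krtap7-1 (−6.5) and Krtap16-4 (−6.28), a family of near-identical copies whose reads could be shared.

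Genes of the outer epidermis and of its defences were higher in the same libraries at 2 weeks. The alarmins S100a8 and S100a9, which keratinocytes make when stressed and neutrophils carry, went from 6.68 ± 2.54 to 183 ± 52.4 (4.59, SE 0.93, limma adjusted p = 0.000904) and from 5.23 ± 2.31 to 127 ± 49.8 (4.36, SE 0.85, adjusted p = 0.000643). The beta-defensin Defb14 went from 1.04 ± 0.766 to 27.5 ± 11.7 (3.79, SE 0.55, adjusted p = 3.18e-05), and A2m, a protease inhibitor, from 0.881 ± 0.363 to 26.5 ± 6.09 (3.86, SE 0.42, adjusted p = 8.59e-07). Of 18 antimicrobial peptides and alarmins 12 rose and 1 fell (12 and 1 adjusted over the list alone, fry adjusted p = 0.000948, adjusted p = 0.215 with an estimated correlation). Of 18 late cornified envelope genes 17 rose (17 adjusted over the list alone), with a median of 2.19 (fry adjusted p = 0.00117, adjusted p = 0.421 with an estimated correlation). Its largest changes were Lce1l (51.1 ± 11.5 to 318 ± 72.8; 2.61, SE 0.4, adjusted p = 5.54e-05) and Lce1k (2.58), again a family of similar copies. In the IL-1 and IL-36 family 12 of 17 rose (12 adjusted over the list alone, fry adjusted p = 7.69e-05, adjusted p = 0.215 with an estimated correlation). The IL-36 cytokines led them, Il1f8 (5.09 ± 1.15 to 55.8 ± 14.9; 3.2, SE 0.46, adjusted p = 3.25e-05) and Il1f6 (2.96 ± 0.605 to 30.5 ± 8.62; 2.96, SE 0.52, adjusted p = 0.000265).

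Further lists that rose at 2 weeks were sebaceous gland genes, with 13 of 20 (13 adjusted over the list alone, fry adjusted p = 0.000537, adjusted p = 0.225 with an estimated correlation). They included Scd1, a desaturase of sebum lipids (274 ± 13.8 to 1220 ± 335; 2.11, SE 0.35, limma adjusted p = 0.000143), and Mgst1 (1.88). Complement and acute phase genes rose in 6 of 20 (6 adjusted over the list alone, fry adjusted p = 0.000272, adjusted p = 0.215 with an estimated correlation). The 2 largest changes there were the acute phase proteins Orm1 (49.5 ± 7.5 to 318 ± 93.3; 2.62, SE 0.44, adjusted p = 0.00015) and Orm2 (2.26). Epidermal lipid and barrier enzymes rose in 12 of 22 (13 adjusted over the list alone, fry adjusted p = 0.0174, adjusted p = 0.643 with an estimated correlation). Among them were Abca12, the lipid transporter of lamellar granules (5.79 ± 0.702 to 20.8 ± 2.17; 1.68, SE 0.27, adjusted p = 0.000109), and the lipase Lipn (2.47). Of 30 nuclear genes of the mitochondrial respiratory chain 18 rose and 1 fell (18 and 1 adjusted over the list alone, fry adjusted p = 0.0281, adjusted p = 0.644 with an estimated correlation). Ndufa4 (1.97) and Ndufa5 (1.37) changed most. Skeletal muscle genes rose in 16 of 23 and fell in 1 (17 and 1 adjusted over the list alone, fry adjusted p = 0.00424, adjusted p = 0.544 with an estimated correlation). Mb, the oxygen carrier of muscle, went from 3.86 ± 0.981 to 42.7 ± 18.8 (3.1, SE 0.37, adjusted p = 2.89e-06), and Ckmt2 also rose (3.27). The barrier call was lost without the library labelled cKO replicate 4 (0.0531). The mitochondrial call was lost without WT replicate 4 (0.052) or without cKO replicate 1 (0.0604), 3 (0.0697) or 4 (0.0684).

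Collagen and cell cycle genes were lower at 2 weeks, less firmly. Col1a1, the main collagen of the dermis, fell from 3880 ± 406 to 502 ± 202 (−3.06, SE 0.59, limma adjusted p = 0.000551) and Col5a1 from 207 ± 10.9 to 46.5 ± 23.8 (−2.35, SE 0.43, adjusted p = 0.00034). Of 21 fibroblast and collagen genes 7 fell and 1 rose (9 and 1 adjusted over the list alone, fry adjusted p = 0.047, adjusted p = 0.789 with an estimated correlation). Of 29 cell cycle genes 13 fell and 1 rose (13 and 1 adjusted over the list alone, fry adjusted p = 0.047, adjusted p = 0.789 with an estimated correlation). Among them were Ube2c (22.9 ± 1.19 to 4.44 ± 2.45; −2.25, SE 0.42, adjusted p = 0.000462) and the mitotic kinase Aurkb (11.3 ± 0.903 to 3.36 ± 2.36; −1.68, SE 0.35, adjusted p = 0.00107). With median-of-ratios scaling neither list passed (0.0976 for both), nor did they with a trend on transcript length removed (0.0971 and 0.158), a setting added after the data were seen. The collagen call was also lost without WT replicate 1, 2, 3 or 4 (0.086, 0.0986, 0.0786, 0.0798) and without cKO replicate 1 or 4 (0.132, 0.0948). The cell cycle call was lost without WT replicate 1, 2, 3 or 4 (0.086, 0.0843, 0.0844, 0.0788) and without cKO replicate 1, 2 or 3 (0.093, 0.106, 0.127).

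The remaining 23 lists did not pass at 2 weeks. The IL-6 and STAT3 response, the pathway that SOCS3 restrains, had 5 of 29 genes higher and 5 lower (fry adjusted p = 0.978). Adipocyte genes had 6 of 14 higher and a median of 0.75 (0.0561), and passed with median-of-ratios scaling (0.0162). Spinous and granular genes had 10 of 24 higher and 1 lower (0.0856). Monocyte and macrophage genes had 7 of 19 higher and 2 lower (0.0683), erythroid genes 5 of 7 higher and 1 lower (0.0683), and eosinophil genes 2 of 4 higher (0.0716). Fry adjusted p was 0.203 for basal keratinocytes, 0.247 for neutrophils, 0.515 for dendritic and Langerhans cells, 0.455 for T and NK cells, for B and plasma cells and for cartilage. It was 0.117 for mast cells and basophils, 0.252 for endothelium, 0.135 for melanocytes and 0.62 for nerve. It was 0.787 for the hyperproliferation-associated keratinocyte genes, whose median was 0.02 and mean −0.05, and 0.736 for the IL-17, IL-22 and IL-20 family. For type 2 cytokines and for matrix proteases, whose median was 0.06 and mean −0.35, it was 0.203. The last lists were at 0.195 for chemokines of neutrophils and monocytes, 0.932 for the interferon response and 0.787 for immediate-early genes. Abpa (4.01), Krt24 (3.91) and Ear5 (3.68) completed the protein-coding genes among the 8 largest rises. The small nucleolar RNA gene Snord2, which lies within another gene and was read without strand, was listed at 0 in all 4 WT libraries and at 635, 571, 563 and 514 FPKM in those labelled cKO.

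In all, 6334 genes differed at 2 weeks, 2509 higher and 3825 lower in the libraries labelled cKO (39.6% higher). Median-of-ratios scaling gave 3296 higher and 3623 lower (47.6% higher), and 2481 and 3510 passed in both. Without the library labelled cKO replicate 1 the count was 3965, and without the library of lowest median in every group, an alternative added after the data were seen, it was 5479.

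At 8 weeks markers of basal keratinocytes, dermis, fat, vessels and hair were higher in the libraries labelled cKO than in WT. Socs3 was called higher too as deposited, against the label, but not after scaling. Markers of B cells and mast cells were lower. These 7 lists passed under both scalings, beside the receptor signal and low medians of WT. Col17a1, a hemidesmosome collagen of basal keratinocytes, went from 22.5 ± 13.7 in WT to 218 ± 48.5 in cKO (3.35, SE 0.44, limma adjusted p = 4.98e-06). The integrin Itga6 went from 1.57 ± 1.72 to 24.4 ± 9.15 (3.43, SE 0.49, adjusted p = 1.3e-05). Of 12 basal keratinocyte genes 11 rose (11 adjusted over the list alone, fry adjusted p = 1.04e-05, adjusted p = 0.594 with an estimated correlation), with a median of 2.0 as deposited and 1.13 after scaling. Fibroblast and collagen genes rose in 20 of 21 (20 adjusted over the list alone, fry adjusted p = 1.57e-05, adjusted p = 0.594 with an estimated correlation), for example Col6a1 (37.7 ± 20.6 to 345 ± 148; 3.18, SE 0.55, adjusted p = 8.15e-05). Adipocyte genes rose in 12 of 14 (12 adjusted over the list alone, fry adjusted p = 0.000192, adjusted p = 0.81 with an estimated correlation). Their largest changes were Car3, a carbonic anhydrase of fat and muscle (19.1 ± 7.67 to 334 ± 120; 4.07, SE 0.36, adjusted p = 1.05e-07), and the lipid droplet protein Plin1 (1.04 ± 0.831 to 14.4 ± 8.5; 2.82, SE 0.55, adjusted p = 0.000277).

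Endothelial genes rose in 13 of 16 at 8 weeks (13 adjusted over the list alone, fry adjusted p = 0.000192, adjusted p = 0.895 with an estimated correlation). Pecam1, an adhesion molecule of vessel walls, went from 5.77 ± 1.61 to 23.9 ± 7.33 (1.85, SE 0.23, limma adjusted p = 3.56e-06). Hair genes rose in 20 of 26 (20 adjusted over the list alone, fry adjusted p = 0.00124, adjusted p = 0.946 with an estimated correlation), the opposite of 2 weeks. Krt71 spread widely between the libraries labelled cKO (53.3 ± 56.8, against 0.792 ± 0.778 in WT; 4.23, SE 0.93, adjusted p = 0.000737) and its call was lost with array quality weights (0.0719). Removing a length trend, a setting added after the data were seen, ended the hair (0.238) and the endothelial call (0.112). Of 4 measured B and plasma cell genes 3 fell (3 adjusted over the list alone, fry adjusted p = 1.41e-05, adjusted p = 0.00281 with an estimated correlation). Among them was Cd79a of the B cell receptor (2.88 ± 0.767 to 0.414 ± 0.266; −1.46, SE 0.16, adjusted p = 7.56e-07). That list also rose in WT from 2 to 8 weeks, so its fall cannot be told from the receptor signal. Of 12 mast cell and basophil genes 4 fell and 1 rose (4 and 1 adjusted over the list alone, fry adjusted p = 0.0188, adjusted p = 0.063 with an estimated correlation). The mast cell protease Cma1 fell from 247 ± 60.1 to 57.8 ± 36.5 (−2.31, SE 0.43, adjusted p = 0.000156) and Mcpt4 from 325 ± 85.1 to 90.8 ± 56.1 (−2.03, SE 0.37, adjusted p = 0.000129). The mast cell call was lost without WT replicate 2 (0.0728).

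Another 17 lists rose at 8 weeks with the values as deposited and did not pass as higher with median-of-ratios scaling, which removes the general shift of 0.82. After scaling the fry direction was down in 6 of them. Mean changes stayed positive, for example, for hyperproliferation-associated genes (1.65 before and 0.84 after scaling), skeletal muscle (1.65 and 0.75), nerve (1.4 and 0.55, adjusted p = 0.0585), immediate-early genes (1.5 and 0.52) and IL-1 and IL-36 genes (1.22 and 0.36). With the trend on transcript length removed no list of the 17 passed as higher. Complement and acute phase genes rose in 10 of 20 and fell in 5 (10 and 6 adjusted over the list alone, fry adjusted p = 6.1e-05, adjusted p = 0.594 with an estimated correlation). After scaling they were lower (0.032). T and NK cell genes rose in 7 of 19 and fell in 2 (6 and 2 adjusted over the list alone, fry adjusted p = 0.00653, adjusted p = 0.732 with an estimated correlation). They were likewise lower after scaling (0.00559). Within the IL-6 and STAT3 response 16 of 29 rose and 2 fell (16 and 2 adjusted over the list alone, fry adjusted p = 0.00175, adjusted p = 0.946 with an estimated correlation, 0.71 after scaling). They included haptoglobin (Hp, 9.54 ± 2.98 to 88 ± 45.6; 2.94, SE 0.46, limma adjusted p = 2.91e-05) and the STAT target Pim1 (2.37 ± 2.01 to 22.5 ± 11.5; 2.79, SE 0.55, adjusted p = 0.000266). IL-1 and IL-36 genes rose in 10 of 17 (10 adjusted over the list alone, fry adjusted p = 4.12e-05, adjusted p = 0.895 with an estimated correlation, 0.214 after scaling). Il1f8 went from 2.05 ± 1.36 to 30.4 ± 21.8 (3.14, SE 0.5, adjusted p = 3.8e-05). Hyperproliferation-associated keratinocyte genes rose in 16 of 28 (10 adjusted over the list alone, fry adjusted p = 0.00553, adjusted p = 0.972 with an estimated correlation, 0.199 after scaling). The wound keratin Krt6a went from 8.15 ± 2.31 to 128 ± 61.2 (3.72, SE 0.48, adjusted p = 3.94e-06). Cell cycle genes rose in 22 of 29 and fell in 1 (23 and 1 adjusted over the list alone, fry adjusted p = 0.00178, adjusted p = 0.946 with an estimated correlation), with a median of −0.01 after scaling (0.754). The gene that fell was Tyms, thymidylate synthase (52 ± 20 to 9.76 ± 1.12; −2.23, SE 0.22, adjusted p = 4.53e-07).

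The other 11 of these 17 lists were barrier enzymes (18 of 22 higher, 19 adjusted over the list alone, fry adjusted p = 0.000192, adjusted p = 0.895 with an estimated correlation), matrix proteases (12 of 19, 12 alone; 0.000192, 0.946) and sebaceous gland (11 of 20, 10 alone; 0.000192, 0.946), with the same quantities in the same order. Next were nerve and Schwann cells (10 of 13 higher and 1 lower, 11 and 1 alone; 0.000192, 0.942), skeletal muscle (17 of 23, 18 alone; 0.00102, 0.942) and the IL-17, IL-22 and IL-20 family (5 of 12, 5 alone; 0.00553, 0.942). They continued with spinous and granular genes (11 of 24, 11 alone; 0.00834, 0.946), immediate-early genes (10 of 17, 9 alone; 0.0164, 0.946) and cartilage (9 of 14 higher and 2 lower, 10 and 2 alone; 0.0212, 0.946). The last were type 2 cytokines (7 of 18 higher and 2 lower, 7 and 2 alone; 0.0231, 0.594) and the interferon response (18 of 30 higher and 1 lower, 18 and 1 alone; 0.0231, 0.946). After scaling the median was −0.06 for spinous genes (0.754), −0.38 for type 2 cytokines (0.0774) and −0.01 for the interferon response (0.901). For cartilage the median was 0.37 where fry pointed down (0.938). Abca12 of the barrier list went from 0.631 ± 0.358 to 10.2 ± 3.68 (2.74, SE 0.3, limma adjusted p = 7.78e-07). Mmp2 of the matrix proteases, a gelatinase, went from 102 ± 51.1 to 380 ± 154 (1.91, SE 0.32, adjusted p = 5.2e-05). Far2 of the sebaceous list, which makes wax alcohols, went from 5.12 ± 3.24 to 70.1 ± 19.4 (3.68, SE 0.36, adjusted p = 4.09e-07) and the desmosomal cadherin Dsc1 of the spinous list from 1.39 ± 0.517 to 46.6 ± 28.7 (4.11, SE 0.45, adjusted p = 8.6e-07). Without WT replicate 3 the calls of T and NK cells (0.0911), cartilage (0.084), immediate-early genes (0.0979), interferon response (0.084), spinous genes (0.084) and type 2 cytokines (0.152) were lost. Cartilage was also lost without WT replicate 1 (0.0754) and cKO replicate 2 (0.0603) or 4 (0.0642). So were immediate-early genes and interferon response without cKO replicate 4 (0.0517, 0.0627), and type 2 cytokines without cKO replicate 1 (0.0507) or 3 (0.0501).

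In 10 lists no change passed at 8 weeks as deposited, and 8 of them were called lower with median-of-ratios scaling. Of 12 neutrophil genes 3 were lower (fry adjusted p = 0.144, 2.32e-05 after scaling). Of 19 monocyte and macrophage genes 3 were higher and 2 lower (0.26, 0.0233 after scaling), and of 16 dendritic and Langerhans cell genes 2 were higher and 2 lower (0.52, 0.000156 after scaling). Of 4 eosinophil genes 1 was lower (0.26, 0.000167 after scaling) and of 30 mitochondrial genes 11 were higher and 2 lower (0.173, 0.0132 after scaling). Melanocyte (0.825, 0.032 after scaling), antimicrobial (0.623, 0.0269) and chemokine genes (0.789, 0.0132) were likewise called lower after scaling. Erythroid (0.26, 0.183) and late cornified envelope genes (0.942, 0.12) passed under neither.

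In all, 9307 genes differed at 8 weeks, 8801 higher and 506 lower in the libraries labelled cKO (94.6% higher). With median-of-ratios scaling 4790 differed, 1918 higher and 2872 lower (40% higher). Both scalings shared 1917 higher and 506 lower genes. The 8 largest rises by the fixed rule were all small RNA genes. Mir675 was listed at 0 in the 3 WT libraries and at 390, 1220, 159 and 447 FPKM in those labelled cKO, and Snora28 at 0 in WT and at 126, 99.4, 46.2 and 53.4 FPKM. In an order without small RNA genes, chosen after the values were seen, Krt80, a keratin of differentiating epithelium, led the rises (1.39 ± 1.21 to 74.1 ± 48.3; 4.88, SE 0.73, limma adjusted p = 1.84e-05). It was followed by the endosomal GTPase Rab7 (8 ± 7 to 177 ± 9.76; 4.8, SE 0.49, adjusted p = 4.61e-07) and the chaperone Calr (4.55). Zfp488, a transcriptional repressor, led the falls of protein-coding genes (140 ± 57.2 to 5.56 ± 2.29; −4.42, SE 0.3, adjusted p = 4.74e-09), with the photoreceptor kinase Grk1 (16.7 ± 7.22 to 0.732 ± 0.328; −3.29, SE 0.24, adjusted p = 9.83e-09).

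At 10 weeks, inflammatory mediators and immediate-early genes were much higher in the libraries labelled cKO, in which Socs3 was also higher, against the label. Il6, the cytokine upstream of STAT3, was 0.256 ± 0.314 in WT and 69.4 ± 32.1 in cKO (5.72, SE 0.3, limma adjusted p = 4.17e-11). Cxcl1, which attracts neutrophils, was 0.629 ± 0.417 and 162 ± 66.3 (6.59, SE 0.43, adjusted p = 1.32e-09), and Ptgs2, the inducible cyclooxygenase, 0.471 ± 0.328 and 35.4 ± 7.44 (4.63, SE 0.25, adjusted p = 6.87e-11). The nuclear receptor Nr4a1 was 3.59 ± 1.03 and 290 ± 40.6 (6, SE 0.64, adjusted p = 1.12e-06). The AP-1 subunit Fosl1 went from 0.078 ± 0.0964 to 42.6 ± 14.8 (5.28, SE 0.35, adjusted p = 1.62e-09). Its relatives Fosb and Fos went from 1.64 ± 1.1 to 88.4 ± 32.9 (5.1, SE 0.83, adjusted p = 0.00014) and from 5.41 ± 3.7 to 159 ± 40.9 (4.86, SE 0.78, adjusted p = 0.000128). The rule takes only genes whose libraries do not overlap between the groups, so the lack of overlap in these genes is no separate evidence. Ptgs2 and Fos, and Lor and Gimap1 among the falls, come from an order without small RNA genes that was chosen after the values were seen.

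Of 17 immediate-early genes 15 rose at 10 weeks (17 adjusted over the list alone), with a median of 2.96 (fry adjusted p = 0.000132, adjusted p = 0.327 with an estimated correlation). The IL-6 and STAT3 response rose in 17 of 29 and fell in 1 (18 and 1 adjusted over the list alone, fry adjusted p = 1.78e-05, adjusted p = 0.327 with an estimated correlation). Tnfaip6, a hyaluronan-binding protein of inflamed tissue, went from 5.96 ± 1.53 to 135 ± 29.2 (4.29, SE 0.28, limma adjusted p = 1.28e-09). In the IL-17, IL-22 and IL-20 family 7 of 12 rose (9 adjusted over the list alone, fry adjusted p = 2.34e-06, adjusted p = 0.327 with an estimated correlation). Among them were Ccl20, the ligand of CCR6 (2.8 ± 2.79 to 78.5 ± 25; 4.57, SE 0.44, adjusted p = 3.61e-07), and Nfkbiz (5.34 ± 2.7 to 66.4 ± 23.2; 3.44, SE 0.32, adjusted p = 2.5e-07). Chemokines of neutrophils and monocytes rose in 9 of 16 (9 adjusted over the list alone, fry adjusted p = 5.07e-06, adjusted p = 0.327 with an estimated correlation). They included Cxcl2 (0.293 ± 0.211 to 17.3 ± 7.87; 3.75, SE 0.25, adjusted p = 1.32e-09). IL-1 and IL-36 genes rose in 10 of 17 (11 adjusted over the list alone, fry adjusted p = 7.85e-06, adjusted p = 0.327 with an estimated correlation). Il1b went from 0.561 ± 0.523 to 15.6 ± 4.32 (3.43, SE 0.25, adjusted p = 5.7e-09). Complement and acute phase genes rose in 10 of 20 (11 adjusted over the list alone, fry adjusted p = 2.34e-06, adjusted p = 0.327 with an estimated correlation). Matrix proteases rose in 9 of 19 (9 adjusted over the list alone, fry adjusted p = 9.1e-05, adjusted p = 0.401 with an estimated correlation).

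Markers of myeloid and antigen-presenting cells moved with these genes. Monocyte and macrophage genes rose in 13 of 19 at 10 weeks (14 adjusted over the list alone, fry adjusted p = 0.00011, adjusted p = 0.363 with an estimated correlation). An example is the endotoxin co-receptor Cd14 (5.29 ± 1.5 to 26.9 ± 7.63; 2.14, SE 0.22, limma adjusted p = 6.94e-07). Dendritic and Langerhans cell genes rose in 10 of 16 and fell in 1 (11 and 1 adjusted over the list alone, fry adjusted p = 8.29e-05, adjusted p = 0.363 with an estimated correlation). Langerin (Cd207) went from 10.8 ± 2.57 to 39.9 ± 7.95 (1.79, SE 0.26, adjusted p = 3.87e-05). T and NK cell genes rose in 7 of 19 and fell in 1 (8 and 1 adjusted over the list alone, fry adjusted p = 0.00393, adjusted p = 0.728 with an estimated correlation, 0.0726 with median-of-ratios scaling). Il2rb, a receptor chain for IL-2 and IL-15, went from 0.935 ± 0.35 to 5.7 ± 0.633 (1.8, SE 0.25, adjusted p = 2.45e-05). Of 12 neutrophil genes 2 rose (2 adjusted over the list alone, fry adjusted p = 0.0109, adjusted p = 0.86 with an estimated correlation, 0.283 with median-of-ratios scaling). Of 4 B and plasma cell genes 1 fell (1 adjusted over the list alone, fry adjusted p = 0.0412, adjusted p = 0.327 with an estimated correlation). That call was lost without any 1 of WT replicates 1 (0.18) and 2 (0.0715) and cKO replicates 1 to 4 (0.0572, 0.056, 0.0738, 0.0763).

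Epidermal and stromal lists also passed at 10 weeks. Basal keratinocyte genes rose in 5 of 12 and fell in 1 (6 and 1 adjusted over the list alone, fry adjusted p = 0.0019, adjusted p = 0.536 with an estimated correlation). Itga6 went from 6.12 ± 5.96 to 48.4 ± 16.2 (3.05, SE 0.49, limma adjusted p = 0.000134). Sebaceous genes rose in 9 of 20 (12 adjusted over the list alone, fry adjusted p = 0.000703, adjusted p = 0.452 with an estimated correlation). Barrier enzymes rose in 11 of 22 (12 adjusted over the list alone, fry adjusted p = 0.0109, adjusted p = 0.707 with an estimated correlation). Endothelial genes rose in 7 of 16 (7 adjusted over the list alone, fry adjusted p = 0.0178, adjusted p = 0.728 with an estimated correlation). The leukocyte adhesion molecule Sele changed by 1.32 (SE 0.22, adjusted p = 0.000204). Hyperproliferation-associated genes rose in 11 of 28 (14 adjusted over the list alone, fry adjusted p = 0.026, adjusted p = 0.728 with an estimated correlation). Among them was the EGF receptor ligand Hbegf (2.15 ± 0.269 to 31.7 ± 12.9; 3.3, SE 0.42, adjusted p = 9.57e-06). The interferon response rose in 9 of 30 (9 adjusted over the list alone, fry adjusted p = 0.026, adjusted p = 0.728 with an estimated correlation). Its examples are Cxcl10 (0.807 ± 0.403 to 30.4 ± 20.1; 3.93, SE 0.42, adjusted p = 1.16e-06) and Irf1 (7.89 ± 0.873 to 73.3 ± 15.3; 3.05, SE 0.26, adjusted p = 8.59e-08). Fibroblast and collagen genes rose in 10 of 21 (10 adjusted over the list alone, fry adjusted p = 0.0083, adjusted p = 0.702 with an estimated correlation). Type 2 cytokines rose in 6 of 18 and fell in 2 (6 and 2 adjusted over the list alone, fry adjusted p = 0.00991, adjusted p = 0.796 with an estimated correlation). Median-of-ratios scaling ended the hyperproliferation (0.0746), interferon (0.137), collagen (0.0651) and type 2 calls (0.204). Removing the trend on transcript length ended the endothelial (0.118), barrier (0.0639), collagen (0.124) and interferon calls (0.124), and those of neutrophil (0.0896) and B cell genes (0.116) given above. Without WT replicate 3 the endothelial (0.0611), barrier (0.0678), hyperproliferation (0.147), interferon (0.0734) and type 2 calls (0.0678) were lost. So were hyperproliferation without WT replicate 2 (0.0629) or cKO replicate 3 (0.0774) and interferon without WT replicate 1 (0.0691).

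Among transcripts that fell at 10 weeks, erythroid genes fell in 4 of 7 (6 adjusted over the list alone, fry adjusted p = 0.0042, adjusted p = 0.327 with an estimated correlation). The haemoglobin gene Hba-a1, which has a near-identical copy, fell from 2520 ± 496 to 534 ± 231 (−2.34, SE 0.51, limma adjusted p = 0.00196). Lor, loricrin of the cornified envelope, fell from 1220 ± 451 to 197 ± 61.8 (−2.62, SE 0.56, adjusted p = 0.00176). Zfp488 changed by −3.32 (SE 0.3, adjusted p = 2.02e-07) and Gimap1, a lymphocyte GTPase, by −2.4 (SE 0.3, adjusted p = 7.43e-06). Both were high only in the WT libraries with the receptor signal, Zfp488 at 140 and 90 FPKM in WT at 8 and 10 weeks against 5.56 to 8.09 FPKM in the other groups, and Gimap1 at 15.7 and 15.4 against 1.92 to 3.33 FPKM. The other 13 lists did not pass, with fry adjusted p of 0.643 for hair (1 of 26 higher, 2 lower), 0.154 for spinous and granular genes, 0.11 for mast cells and for skeletal muscle, 0.876 for eosinophils, whose median was −0.1 and mean 0.11, and 0.45 for cartilage. It was 0.0783 for adipocytes, 0.147 for melanocytes, 0.0908 for nerve, 0.0853 for antimicrobial genes, 0.404 for the late cornified envelope, 0.643 for the cell cycle and 0.274 for the respiratory chain. With median-of-ratios scaling skeletal muscle was called lower (0.0477). Within the antimicrobial list, S100a8 lay at 7.42, 13.4, 838 and 16.5 FPKM in the libraries labelled cKO, so that 1 library held most of it.

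In all, 3577 genes differed at 10 weeks, 2927 higher and 650 lower in the libraries labelled cKO (81.8% higher). With median-of-ratios scaling 3801 differed, 1936 higher and 1865 lower (50.9% higher). Both scalings shared 1935 higher and 649 lower genes. Without WT replicate 3 the count was 1810.

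**Figure D3:**
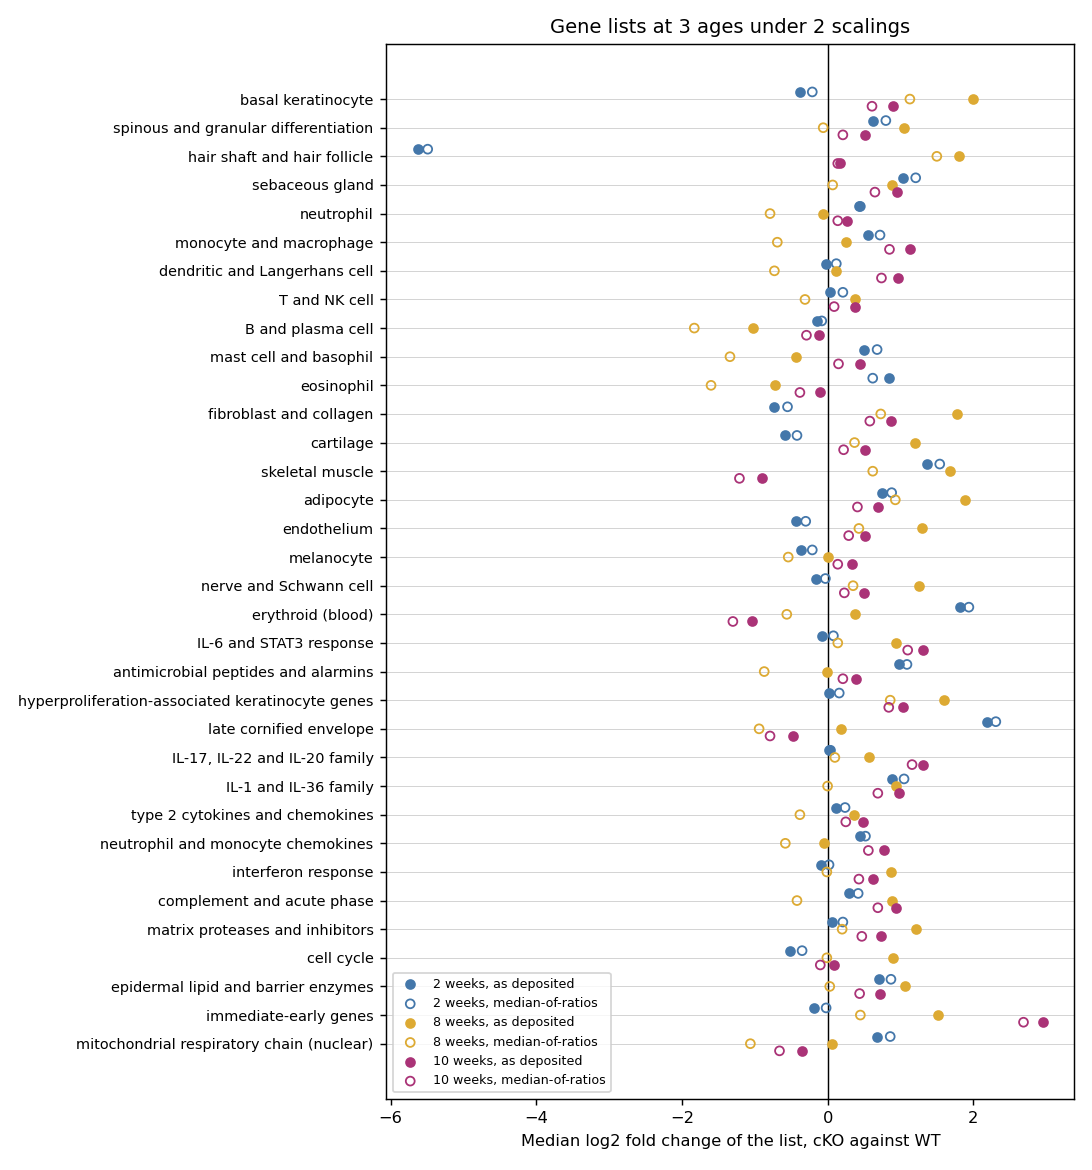
Median change in log2(FPKM + 1) of the measured genes of 34 lists (x axis) between libraries labelled cKO and WT at 2, 8 and 10 weeks, with filled points for the values as deposited and open points for median-of-ratios scaling. At 8 weeks scaling moves nearly the whole set of points by the general shift of 0.82 and turns several lists, complement among them, to the other side of 0.

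Between 2 and 8 weeks hair, collagen and basal keratinocyte transcripts fell in the WT ears. Krt71 changed by −8.97 (SE 0.93, limma adjusted p = 1.31e-07). All 26 hair genes fell (26 adjusted over the list alone, fry adjusted p = 2.9e-09, adjusted p = 0.244 with an estimated correlation). Of 21 fibroblast and collagen genes 19 fell and 1 rose (19 and 1 adjusted over the list alone, fry adjusted p = 9.44e-07, adjusted p = 0.568 with an estimated correlation), and 11 of 12 basal keratinocyte genes fell (11 adjusted over the list alone, fry adjusted p = 1.06e-06, adjusted p = 0.568 with an estimated correlation). Endothelial genes fell in 13 of 16 and rose in 1 (fry adjusted p = 6.49e-05, adjusted p = 0.864 with an estimated correlation). Nerve genes fell in 10 of 13 and rose in 1 (fry adjusted p = 0.000312, adjusted p = 0.956 with an estimated correlation). B and plasma cell genes rose in 3 of 4 (fry adjusted p = 1.06e-06, adjusted p = 0.0239 with an estimated correlation) and eosinophil genes in 2 of 4 (fry adjusted p = 0.00363, adjusted p = 0.2 with an estimated correlation). Antimicrobial genes rose in 8 of 18 with 3 lower (fry adjusted p = 0.016, adjusted p = 0.0669 with an estimated correlation), but not without WT replicate 1 of 8 weeks (0.079). In these 5 lists the counts adjusted over the list alone were the same. The directions of these 8 lists held under both scalings. Another 11 lists were lower as deposited and did not pass after scaling. Among them was skeletal muscle, with 16 of 23 lower and 2 higher (17 and 2 adjusted over the list alone, fry adjusted p = 0.00671, adjusted p = 0.956 with an estimated correlation, 0.504 after scaling). Myh4 fell from 25 to 0.753 FPKM and Atp2a1 from 63.2 to 5.21 FPKM, whereas myoglobin (Mb) rose from 3.86 ± 0.981 to 179 ± 104 (5.06, SE 0.4, limma adjusted p = 5.25e-09). The whole count of 10599 genes was 1370 higher and 9229 lower as deposited and 4354 higher and 4295 lower after scaling, around a general shift of −0.94. The WT libraries of 8 weeks are those with the receptor signal.

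From 8 to 10 weeks the WT libraries moved in common by 0.55, and 4440 genes differed, 4357 higher and 83 lower, against 270 higher and 811 lower with median-of-ratios scaling. Skeletal muscle genes rose in 16 of 23 (18 adjusted over the list alone, fry adjusted p = 0.0102, adjusted p = 0.51 with an estimated correlation) and basal keratinocyte genes in 7 of 12 (9 adjusted over the list alone, fry adjusted p = 0.0102, adjusted p = 0.628 with an estimated correlation). After scaling neither passed (0.0542 and 0.0562), nor did the collagen, cell cycle and barrier lists, which had been higher as deposited (0.808 for each after scaling). Of 4 B and plasma cell genes 1 fell (2 adjusted over the list alone, fry adjusted p = 0.0212, adjusted p = 0.00985 with an estimated correlation), under both scalings. Without WT replicate 2 of 10 weeks the muscle, basal and B cell calls were lost (0.0642 for each). The B cell call was also lost without WT replicate 1 of 8 weeks (0.102) or replicate 3 of 10 weeks (0.0568). The count of changed genes rested on single libraries and was 2547 and 1299 without WT replicates 1 and 3 of 8 weeks and 2309 and 664 without WT replicates 1 and 2 of 10 weeks.

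From 2 to 8 weeks mast cell and pigment cell transcripts fell in the libraries labelled cKO, and the number of genes that differed depended on the setting. Hdc, which makes histamine and is used by mast cells, basophils and neutrophils, went from 15.5 ± 1.33 to 1.37 ± 0.217 (−2.8, SE 0.16, limma adjusted p = 9.6e-10). Of 12 mast cell and basophil genes 7 fell (7 lower and 1 higher adjusted over the list alone, fry adjusted p = 0.00441, adjusted p = 0.0876 with an estimated correlation). Of 8 melanocyte genes 3 fell (7 adjusted over the list alone, fry adjusted p = 0.00704, adjusted p = 0.0876 with an estimated correlation). The hair keratin Krt84 fell from 16.2 ± 8.71 to 1.32 ± 1.14 (−2.86, SE 0.31, adjusted p = 1.84e-05). The hair list, which does not hold Krt84, pointed the other way without passing (mean 1.08, 15 of 26 higher adjusted over the list alone, fry adjusted p = 0.079), and the mean of Krt71 went from 8.97 to 53.3 FPKM. Ifi27l2a, an interferon-induced gene, rose from 35.8 ± 14.8 to 172 ± 57.7 (2.27, SE 0.27, adjusted p = 5.03e-05). The matrix protein Comp rose from 2.91 ± 1.71 to 19 ± 10.3 (2.3, SE 0.43, adjusted p = 0.00656) and Myoc, myocilin, from 56.9 ± 34.1 to 431 ± 305 (2.75, SE 0.43, adjusted p = 0.00161). Socs3 did not pass (−0.06, SE 0.43, adjusted p = 0.977). In all 174 genes differed, 54 higher and 120 lower, and 4 of 35 splits, the real one included, gave as many. Array quality weights gave 5099 with the balance turned, 3161 higher and 1938 lower. The count was 75 without the library labelled cKO replicate 3 of 2 weeks and 96 without replicate 4 of 8 weeks. With only these 2 groups in the fit 9 genes passed, and Krt84 (0.0693), Ifi27l2a (0.0727), Comp (0.282) and Myoc (0.209) did not.

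From 8 to 10 weeks the libraries labelled cKO gained the inflammatory transcripts, in a comparison that holds no WT library. Il6 rose by 5.51 (SE 0.27, limma adjusted p = 2.9e-11), Cxcl1 by 5.42 (SE 0.4, adjusted p = 1.32e-08), Fosl1 by 4.39 (SE 0.33, adjusted p = 1.38e-08) and Socs3 by 2.65 (SE 0.43, adjusted p = 0.000693; exact permutation p = 0.0286). Spon2, a matrix protein that binds bacteria, changed by −2.26 (SE 0.26, adjusted p = 8.39e-06). Chemokines of neutrophils and monocytes rose in 6 of 16 (10 adjusted over the list alone, fry adjusted p = 5.18e-06, adjusted p = 0.00766 with an estimated correlation). The IL-17, IL-22 and IL-20 family rose in 8 of 12 (9 adjusted over the list alone, fry adjusted p = 6.8e-06, adjusted p = 0.00766 with an estimated correlation), and mast cell and basophil genes in 5 of 12 (10 adjusted over the list alone, fry adjusted p = 0.000572, adjusted p = 0.0348 with an estimated correlation). Immediate-early genes rose in 9 of 17 (17 adjusted over the list alone, fry adjusted p = 0.0041, adjusted p = 0.0808 with an estimated correlation). The IL-6 and STAT3 response rose in 7 of 29 (11 adjusted over the list alone, fry adjusted p = 0.000572, adjusted p = 0.0688 with an estimated correlation) and monocyte and macrophage genes in 6 of 19 (12 adjusted over the list alone, fry adjusted p = 0.00105, adjusted p = 0.0688 with an estimated correlation). Hair genes fell in 6 of 26 (20 adjusted over the list alone, fry adjusted p = 0.0104, adjusted p = 0.0933 with an estimated correlation). Erythroid genes fell in 2 of 7 (5 adjusted over the list alone, fry adjusted p = 0.00641, adjusted p = 0.0921 with an estimated correlation). Neutrophil genes (1 of 12 higher and 1 lower; 2 and 1 adjusted over the list alone), dendritic cell genes (1 of 16; 4 alone) and complement genes (1 of 20; 2 alone) also passed as higher. Their values were fry adjusted p = 0.00696, 0.00665 and 0.00367 and adjusted p = 0.39, 0.0933 and 0.0688 with an estimated correlation. In all 432 genes differed, 279 higher and 153 lower (64.6% higher, 74.2% with median-of-ratios scaling). The balance turned with array quality weights (4169, 1496 higher and 2673 lower) and without the library of lowest median in every group (1094, 528 higher and 566 lower). The count was 260 without the library labelled cKO replicate 1 of 8 weeks and 259 and 230 without replicates 2 and 3 of 10 weeks.

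Interaction contrasts compared the difference between the labelled genotypes across ages. They also hold the WT libraries of 8 and 10 weeks. They carry the Socs3 levels given above, which were called against the label under both scalings only at 10 weeks. From 2 to 8 weeks it differed for 9038 genes (8058 higher and 980 lower as deposited, 3484 and 3695 with median-of-ratios scaling, around a general shift of 0.96). Hair genes moved up in 26 of 26 (26 adjusted over the list alone, fry adjusted p = 2.46e-08, adjusted p = 0.139 with an estimated correlation), with Krt71 at 11.17 (SE 1.27, limma adjusted p = 1.77e-06). Basal keratinocyte genes moved up in 11 of 12 (11 adjusted over the list alone, fry adjusted p = 2.04e-05, adjusted p = 0.482 with an estimated correlation). Late cornified envelope genes moved down in 15 of 18 (15 adjusted over the list alone, fry adjusted p = 0.0192, adjusted p = 0.146 with an estimated correlation), a call lost without WT replicate 1 of 8 weeks (0.0639). From 8 to 10 weeks it differed for 1327 genes (124 higher and 1203 lower as deposited, 530 and 108 with scaling, around −0.54). For this count chance was not excluded, since 10 of 100 splits, with the real one, gave as many genes and the highest 5795, and 162 genes passed with only the compared groups in the fit. Chemokines moved up in 6 of 16 (8 adjusted over the list alone, fry adjusted p = 0.00163, adjusted p = 0.00349 with an estimated correlation). Skeletal muscle genes moved down in 16 of 23 (21 adjusted over the list alone, fry adjusted p = 0.00527, adjusted p = 0.138 with an estimated correlation). Il6 differed by 5.62 (SE 0.42, limma adjusted p = 7.11e-08), Cxcl1 by 5.5 (SE 0.61, adjusted p = 1.98e-05) and Fosl1 by 4.3 (SE 0.5, adjusted p = 3.62e-05). From 2 to 10 weeks it differed for 5403 genes (4134 higher and 1269 lower, 2847 and 2516 with scaling, around 0.43). Immediate-early genes moved up in 17 of 17 (17 adjusted over the list alone, fry adjusted p = 0.002, adjusted p = 0.702 with an estimated correlation). The IL-17, IL-22 and IL-20 family moved up in 8 of 12 with 1 lower (8 and 1 adjusted over the list alone, fry adjusted p = 0.000255, adjusted p = 0.641 with an estimated correlation). Late cornified envelope genes moved down in 13 of 18 (14 adjusted over the list alone, fry adjusted p = 0.00347, adjusted p = 0.383 with an estimated correlation). Socs3 differed by 2.47 from 2 to 8 weeks and by 4.06 from 2 to 10 weeks. The count from 8 to 10 weeks rested on single libraries and ran from 310 to 3623 when 1 library was left out.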

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

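All tests of explanations in this part were chosen after the results were seen. Of these, 4 replaced earlier versions whose results had been seen. The earlier test of reads from outside mature transcripts used genes near 0 in the other libraries (48.3% to 80.3% above 0 in the 6 libraries, 10.8% to 16% elsewhere, left open). That of WT library quality used only the 8 largest rises, of which 7 passed (excluded, as now). That of neutrophils used only S100a8 and S100a9, which were below the mean of 8 weeks in 3 of the 4 libraries labelled cKO at 10 weeks, and had excluded them where the present test leaves them open. That of handling picked single libraries by their Fos level, where Il6 reached 1.35 FPKM at most (left open, as now).

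In groups of 4, 226 tests asked whether 1 library lay far from the 3 others. They pointed to 11 gene values, where about 11 would arise by chance, since chance points to about 1 in 20 groups. Among the WT libraries of 2 weeks, replicate 2 was low for Abca12 (4.76 FPKM) and high for Ckmt2 (3.39 FPKM). Replicate 3 was high for Lce1l (68.3 FPKM), and replicate 4 was low for Ndufa5 (39.8 FPKM) and Socs3 (9.71 FPKM). In the libraries labelled cKO, replicate 2 of 2 weeks was low for Lipn (11.4 FPKM), and replicate 1 of 8 weeks was low for Mir546 (123 FPKM) and Rab7 (162 FPKM). At 10 weeks replicate 1 was high for Mir339 (41.2 FPKM) and low for Snord2 (287 FPKM), and replicate 3 was high for Krt6b (632 FPKM). Replicate 4 of 10 weeks had a high total FPKM (594790) and a low median of tested genes (7.32).

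Interaction contrasts found that the difference between the labelled genotypes changed from 2 to 8 weeks for 9038 genes, from 8 to 10 weeks for 1327 and from 2 to 10 weeks for 5403. For the first, the largest values were Rnu73b (12.03), Mir675 (11.87), Krt71 (11.17), Krtap7-1 (10.24), Snord2 (−9.79), Mir680-2 (−5.48), Rpph1 (−4.6) and Ear5 (−4.36), and Socs3 was at 2.47. From 8 to 10 weeks they were Snord2 (9.49), Il6 (5.62), Cxcl1 (5.5), Fosl1 (4.3), Snora43 (−4.93), Mir339 (−4.13), Snora70 (−4.01) and Atp2a1 (−3.82). From 2 to 10 weeks they were Rnu73b (10.09), Snord23 (8.57), Mir23b (8.43), Krt71 (8.09), Snord116l1 (−6.19), Snord116l2 (−6.19), Mir680-1 (−5.76) and Hba-a1 (−5.58), and Socs3 was at 4.06. The values of small RNA genes rest on libraries listed at 0 and are no measure of fold. Leaving out 1 library ended the calls of Snora70 in 10 cases (adjusted p up to 0.128), Mir339 in 7 (0.0773), Snora43 in 2 (0.0654), Snord2 from 8 to 10 weeks in 2 (0.0677), Mir23b in 2 (0.064) and Mir680-2 in 1 (0.0517).

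Other splits of the same libraries were counted for each comparison. Rank spoke against chance for the labelled genotypes at 2 weeks (6334 genes, highest other 1), 8 weeks (9307, 8193) and 10 weeks (3577, 1699). In each 1 of 35 splits was as large (0.0286, the least possible, unadjusted). Rank did likewise for WT from 2 to 8 weeks (10599, 7914) and the libraries labelled cKO from 8 to 10 weeks (432, 45). With 1 of 100 drawn splits it did so for the interactions from 2 to 8 (9038, 8179) and 2 to 10 weeks (5403, 4893). Other splits came near at 8 weeks and in these interactions, so the evidence there is weak. For WT from 8 to 10 weeks (4440, 422) the 10 splits are too few. For the interaction from 8 to 10 weeks chance was not excluded. There 10 of 100 splits reached its 1327 and the highest 5795, for untested reasons. For the libraries labelled cKO from 2 to 8 weeks it was not excluded either (174, with 4 of 35 splits as large). There libraries of the same number deviated alike, but need not be pairs. The 8 splits that part all 4 numbers gave 0 beside the real one, and others up to 2318 and 4169. That grouping came from the same data, so chance stays open.

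Leaving out 1 library moved these counts by over 1.5 times. They were 3965 at 2 weeks without the library labelled cKO replicate 1 and 1810 at 10 weeks without WT replicate 3. From 2 to 8 weeks the libraries labelled cKO gave 75 without replicate 3 of 2 weeks and 96 without replicate 4 of 8 weeks. From 8 to 10 weeks they gave 260 without replicate 1 of 8 weeks and 259 and 230 without replicates 2 and 3 of 10 weeks. WT from 8 to 10 weeks gave 2547 and 1299 without replicates 1 and 3 of 8 weeks and 2309 and 664 without replicates 1 and 2 of 10 weeks. The interaction from 8 to 10 weeks went from 1327 to 310 without WT replicate 2 of 10 weeks and to 3623 without WT replicate 2 of 8 weeks. It was 651 and 584 without WT replicates 1 and 3 of 8 weeks and 671 without WT replicate 1 of 10 weeks. It was 2773, 702 and 781 without replicates 1, 2 and 4 labelled cKO of 8 weeks, and 743, 664 and 659 without replicates 1, 2 and 3 labelled cKO of 10 weeks.

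Olfactory and vomeronasal receptor genes, none of them named in a comparison, were above 0 for 59.8% on average in WT at 8 weeks and 54.2% in WT at 10 weeks. Greater depth was excluded, since the mean relative depth of these 6 libraries was 0.971 of the others, and so was age alone, since no library labelled cKO of 8 or 10 weeks exceeded 7.26%. RNA or DNA from outside mature transcripts may be the source. At least 43% of 121 genes of other tissue-restricted families picked by name were above 0 in each of the 6 libraries, against 13.2% to 23.1% elsewhere, but the limit of 15% set for the others was missed. This stays open, as does a difference of genotype or handling, because no WT library of these ages lacks the signal.

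Hair genes were lower at 2 weeks in the libraries labelled cKO. A trend on transcript length was excluded as the whole cause, since the median was −5.5 with that trend removed. An exchange of the 2 and 8 week labels was excluded too, since 9 genes of early postnatal stage were lower at 8 than at 2 weeks by a median of −0.76 (8 of 9, with Dlk1 at 0.27). A later stage of the tissue could account for part of the pattern, since these genes lay a median of 58.7% of the way from WT at 2 weeks to the libraries labelled cKO at 8 weeks, from −25.8% for Peg3 to 108% for Dlk1. That explanation and an effect of the genotype cannot be told apart here.

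Cytokine and immediate-early genes were higher at 10 weeks in the libraries labelled cKO, and quality of the WT libraries was excluded as the whole cause, since the immediate-early median was 1.83 from 8 to 10 weeks without any WT library. Neutrophils in the tissue may contribute, since their list passed as higher (fry adjusted p = 0.00696, but 0.39 with an estimated correlation) at a median of 0.14, carried by Hdc (2.69, adjusted p = 4.47e-10), which mast cells share. Against them, Stfa2 went only from 10.4 to 20 FPKM, Camp changed by −1.22, and S100a8 lay at 7.42, 13.4 and 16.5 FPKM in 3 of the 4 libraries. The abundant Il1r2 went from 129 to 141 FPKM. It also stands in the IL-1 and IL-36 list, so its level need not come from neutrophils and does not count against them. Of the 22 listed genes 5 stand in other lists too. Handling before RNA extraction could raise immediate-early genes, and the only other group with Fos above 50% of this level, labelled cKO at 2 weeks (75.4%), had Il6 at 0.801% of it. With 1 such group handling stays open, as do neutrophils and an effect of the genotype.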

How the results depend on the processing

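The settings that removed a length trend, left out the library of lowest median in every group, left out small RNA genes or used Eif2s3y as a covariate were chosen after the data were seen. Over all settings, named genes and lists kept direction and side of the threshold in 4776 cases, lost the call in 342 and reversed in 29. Counts, list counts and Socs3 were within 1.5 times or on the same side in 260 cases, moved in 57, passed newly in 3 and lost the call in 2. Without small RNA genes 231 named results were unchanged and 0 were lost. With Eif2s3y 276 were unchanged and 3 were lost. Where no construction is named, the cause was not tested.

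All reversals were of list directions at 8 weeks. With median-of-ratios scaling, which removes the general shift, mean changes became −0.31 for T and NK cells, −0.52 for type 2 cytokines, −0.05 for interferon, −0.46 for complement and −0.08 for the cell cycle, and 0.07 for cartilage, where fry pointed down. With the length trend removed they were −0.31, −0.11, −0.03, −0.08 and −0.06 in the same order without cartilage. Camera, which tests a list relative to other genes, pointed down at both correlations for lists with positive means: spinous (1.21), T and NK cell (0.43), cartilage (1.05), IL-6 and STAT3 (0.96), IL-17 (0.71), type 2 (0.4), interferon (0.74), complement (0.58) and matrix proteases (0.88).

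Camera with an estimated correlation called 0, 2 and 0 lists at 2, 8 and 10 weeks where fry called 11, 24 and 21 (5, 5 and 4 at an unadjusted p under 0.05), and with the preset correlation 14 at 8 weeks, of which 2 were higher and 12 lower where fry gave 22 and 2. Median-of-ratios scaling gave 4790 genes at 8 weeks, 1081 for WT from 8 to 10 weeks and 638 for the interaction from 8 to 10 weeks, and Socs3 at 8 weeks lost its call (0.91, adjusted p = 0.0972). With the length trend removed these were 4377, 849, 552 and 0.78 (adjusted p = 0.157), with 280 genes for the libraries labelled cKO from 2 to 8 weeks and 9 lists at 8 weeks. Array weights, which count libraries unequally, gave 10423 genes at 2 weeks, 8435 at 10 weeks, 5099 and 4169 for the libraries labelled cKO from 2 to 8 and 8 to 10 weeks, and 5064 and 9993 for the interactions from 8 to 10 and 2 to 10 weeks. Socs3 at 2 weeks then passed as lower (−0.98, adjusted p = 0.000194).

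A change of at least 1, which only removes genes, left 3081, 5708 and 1760 at 2, 8 and 10 weeks, 2169 for WT from 8 to 10 weeks and 251 for the libraries labelled cKO over the same ages. With only the compared groups in the fit, and so fewer libraries, 610 and 193 passed there, 9 for the libraries labelled cKO from 2 to 8 weeks and 162 for the interaction from 8 to 10 weeks. A pseudocount of 0.1 gave 112 for the libraries labelled cKO from 2 to 8 weeks, and a filter at 5 FPKM, with fewer genes tested, 98 there and 266 from 8 to 10 weeks. No filter gave 5498 at 10 weeks. Without the library of lowest median in every group the counts were 364 and 1094 for the libraries labelled cKO from 2 to 8 and 8 to 10 weeks and 3536 for the interaction from 8 to 10 weeks, and 10, 18 and 14 lists were called at 2, 8 and 10 weeks.

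With the replicate number as a block, 6282, 8429 and 3281 genes were called at 2, 8 and 10 weeks, and 8296, 187 and 5830 in the interactions from 2 to 8, 8 to 10 and 2 to 10 weeks. Within genotype they were 10488 and 5427 for WT and 444 for the libraries labelled cKO from 8 to 10 weeks. In these comparisons the numbers did not pair libraries, with correlations of deviations from −0.0217 to 0.0383, −0.125 to 0.34 and −0.25 to 0.0467 at 2, 8 and 10 weeks, −0.0481 to −0.00537 and −0.117 to 0.281 for WT, and −0.296 to 0.148. The block ended 21 named calls within ages and 0 of 32 within genotypes.

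Leaving out 1 library at a time, Socs3 ran from −1.24 to −0.38 at 2 weeks (passing at −1.11 and −1.24 without replicates 2 and 3 labelled cKO), from 1.38 to 2.0 at 8 weeks and from 2.99 to 3.46 at 10 weeks. Lists called ran from 8 to 11, 18 to 25 and 16 to 22. Genes ran from 3965 (without cKO replicate 1) to 7207 at 2 weeks, 7462 to 9802 at 8 weeks and 1810 (without WT replicate 3) to 3763 at 10 weeks. For WT they ran from 9867 to 10798 and, from 8 to 10 weeks, from 664 to 6553. For the libraries labelled cKO they ran from 75 to 223 and from 230 to 490. The interactions ran from 8398 to 9593, 310 to 3623 and 3863 to 6355. Read depth is unknown, so what depth limits could not be stated.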

Other observations

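The tests and the named genes of this part were chosen after the values were seen. Some genes were called in the same direction at every age, but sharing between 2 and 8 weeks was below that of independent calls. The comparisons use different libraries, yet they share an estimate of each gene's spread from all libraries. Of the genes called at all 3 ages under both scalings, 173 were higher and 16 lower. Fam83b changed by 2.73, 2.99 and 3.36 at 2, 8 and 10 weeks, the IL-36 cytokine Il1f8 by 3.2, 3.14 and 2.63, and the desmosomal cadherin Dsc1 by 2.25, 4.11 and 3.17. As deposited 663 genes were higher at all 3 ages, where independent calls would give 323, and 16 were lower, where they would give 6. With median-of-ratios scaling the counts were 236 against 60 and 167 against 96. The pairs of ages differed. Higher calls of 2 and 8 weeks shared 1398 genes, fewer than the 1562 of independent calls, and lower calls 27 against 137, with 361 against 444 and 293 against 731 after scaling. For 2 and 10 weeks the counts were 737 against 519 higher and 125 against 176 lower, and 558 against 448 and 394 against 475 after scaling. For 8 and 10 weeks, the ages whose WT libraries carry the receptor signal, they were 2628 against 1822 and 234 against 23, and 879 against 261 and 1200 against 376 after scaling. Genes are not independent, and the shared estimate of spread can favour calls of the same gene at several ages. These expected counts are therefore a guide only.

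Per1 and Per2 of the circadian clock were higher at 10 weeks than at 8 weeks in the libraries labelled cKO. Per1 was 53.1 ± 8.03 FPKM in the libraries labelled cKO at 10 weeks, 8.31 ± 5.31 FPKM at 8 weeks and 10.5 ± 1.3 FPKM in WT at 10 weeks (n = 4, 4 and 3). Its change from 8 to 10 weeks was 2.72 (SE 0.4, limma adjusted p = 0.000185), and that of Per2 was 1.58 (adjusted p = 0.000317). Dbp, an output gene of the clock, was at 49.3 ± 10.6 and 42.6 ± 18.7 FPKM (0.28, limma adjusted p = 0.743). The hour of sampling is not given in the sources used here.

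In the libraries labelled cKO at 10 weeks, replicate 3 held the highest S100a8 (838 FPKM against 7.42, 13.4 and 16.5 FPKM), S100a9 (425 FPKM against 5.13, 13.8 and 18.6 FPKM) and Krt6b (632 FPKM against 28.3, 30.3 and 31.9 FPKM). Hdc was 15.5 ± 1.33, 1.37 ± 0.217 and 14.3 ± 2.01 FPKM in the libraries labelled cKO at 2, 8 and 10 weeks. Changes at a given age also followed transcript length. From the shortest to the longest of 5 equal classes of genes the median change went from 0.22 to −0.28 at 2 weeks, from 0.28 to 0.99 at 8 weeks and from −0.21 to 0.57 at 10 weeks.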
